A study of Homo sapiens with 6 samples.

How the data were processed

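The data were 1 table of the whole series with 60606 genes and 6 columns of values, 3 control and 3 irradiated tumors, each column named for a tumor in the labels. Values are TPM, as deposited by the authors, a measure of transcript share scaled for gene length and for the total within each sample, given to 2 decimals. Per the labels' protocols, libraries were made from total RNA with an Illumina TruSeq RNA kit. The submitters' processing notes name HISAT2, StringTie, RSEM and the genome build hg38, with no versions or order, and the annotation release, the use of strand and any removal of mouse reads are not given in the sources used here. Because TPM keeps no depth, the number of reads behind each value is unknown, no counting interval can be given, and no count test was run. TPM are shares of a total, so a rise in abundant genes lowers the values of others. The columns did not sum to the same total, and fell short of the full total of TPM by 0.143% to 0.198% in controls and by 0.523% to 0.774% in irradiated tumors.

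Genes keep the identifiers and symbols of the table. Gene types, coordinates (GRCh38, the same assembly as hg38), exonic overlap on the same strand, and the length and GC content of the longest transcript came from GENCODE release 29, in which 58396 of the 60606 identifiers were found. That release need not be the one the authors used. None of 18 widely expressed genes was at 0 in any tumor, and 20 genes were at 0 in at least 1 tumor and at 20 TPM or more in at least 3. Genes that overlap others, pseudogenes, duplicated genes and antisense genes are uncertain, because reads can be split between them in more than 1 way.

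The design was fixed before the data were examined. Irradiated and control tumors were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(TPM + 1), a pseudocount of 1 TPM, over the 14140 genes with a mean of at least 1 TPM, with group as the only term, a two-sided test and Benjamini-Hochberg adjustment at 0.05. No pairing term was used, since the labels do not tie tumors of the same number together. Adjusted p-values of single genes are limma's throughout. Of 38 gene lists fixed beforehand, covering polyamines, radiation and stress responses, metabolism, matrix and markers of other cell types, the 34 with at least 5 measured genes were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, and fry tests whether its genes move one way on balance. A gene is called measured where it passed the filter, and the groups of a gene do not overlap where all 3 values of one group lie above all 3 of the other.

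The genes named in the text follow a rule fixed beforehand. It takes SRM, and the 12 genes with the largest log2 fold change in each direction among called genes with a mean of at least 5 TPM in the higher group and no overlap between the groups, leaving out clone names, LOC and LINC names, pseudogenes of ribosomal proteins and genes without a symbol. Where fewer than 12 had passed, those that passed would have been taken, and where none had, the 10 genes with the smallest unadjusted p under the same other conditions. It also takes up to 4 members, with the smallest p in the direction of the list, of each list that was called or held a called gene, and CDKN1A, MDM2, MKI67, ODC1, SMS, AMD1 and SAT1 whatever their test. Some further genes were named after their values were seen, to spell out small counts or to show partners of named genes: SLC3A2, H2BC5, TM7SF2, BHLHE40, MCAM, HSPG2, COL6A1, COL6A2, FN1, H3C2, H1-4, H2AC12, MUC1, MOB4, NUP62, DDX39B, TAX1BP3, P2RX5, PYURF, SERF1B and RNA5-8SN5.

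The fit was tested on simulated data for this comparison, with 14140 genes drawn independently, 200 of them changed in each of 5 draws. It recovered 33.0% of genes changed by a factor of 2 and 78.4% of those changed by a factor of 4, with 5.59% false calls among the calls, and camera called 0 of 170 unchanged lists. Because the simulated genes did not vary together, the 0 of 170 does not show how often camera calls unchanged lists in real tumors. Alternatives fixed beforehand were pseudocounts of 0.1 and 5 TPM, no filter and a minimum mean of 5 TPM, scaling by medians of ratios, quantile normalization, leaving out mitochondrially encoded and ribosomal protein genes, limma without trend, with robust estimates and with sample weights, a replicate block, each tumor left out in turn, and a minimum fold of 1.5. Added after seeing the data were fits on protein-coding genes without overlap, on sums over overlapping genes without pseudogenes, on values corrected for transcript length and GC content with loess, and without control tumor 2 and irradiated tumor 2 together. No sample was left out of the comparison itself, and all 6 columns were used.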

Results

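RNA was sequenced from 6 tumors grown under the skin of NSG mice, a strain without T, B and natural killer cells, from MDA-MB-231, a human breast cancer cell line. Of these, 3 tumors were not irradiated and served as controls, and 3 received a single local X-ray dose of 10 Gy at a volume of about 800 mm3 and were collected 3 days later. No volume or collection time is recorded for the controls, so whether they matched the irradiated tumors in size or time is unknown. The title of the series names spermidine synthase (SRM) secreted by cancer cells and muscle fibrosis after radiotherapy, and the comparison asks which transcripts differed between irradiated and control tumors. Levels are TPM, given below as mean ± SD with n = 3 tumors per group, and fold changes are irradiated minus control on the log2(TPM + 1) scale, which understates changes of low genes. The labels do not say that the tumors came from separate animals, so p-values measure the spread between these samples. The number of reads behind each value is unknown, because TPM keeps no depth. Between 13392 and 14218 genes reached 1 TPM in a tumor. The first principal component held 40.4% of the variance and separated the groups, and the second, with 19.1%, set control tumor 2 apart from the rest. In control tumor 2, ribosomal protein genes took 25.9% of all TPM, against 19.0% to 21.4% in the other 5 tumors.

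Interferon-stimulated genes were higher as a group in irradiated tumors. Genes of glycolysis and skeletal muscle were lower as groups, and so were fibroblast markers, of which 8 of 11 had a fold change below 0. Of 14140 genes tested with limma, 421 passed an adjusted p of 0.05, of which 194 rose and 227 fell. At an unadjusted p under 0.05 there were 2896 genes, and in 3758 genes (26.6%) the groups did not overlap, where chance gives 10%. Of 34 gene lists fixed beforehand and tested with camera, 7 were called higher and 10 lower at a preset correlation of 0.01, and 0 with an estimated correlation. At the preset correlation, splits of the tumors that mixed the groups called 6 to 19 lists. The number of called genes changed with each tumor left out, where the test also has fewer samples. It was 138, 791 and 153 without control tumors 1, 2 and 3, and 127, 192 and 144 without irradiated tumors 1, 2 and 3. It was 186 with control tumor 2 and irradiated tumor 2 left out together. Of 69 called genes among those named by the fixed rule, 25 kept their call with each of the 6 tumors left out in turn, and 44 lost it at least once.

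**Figure D1:**
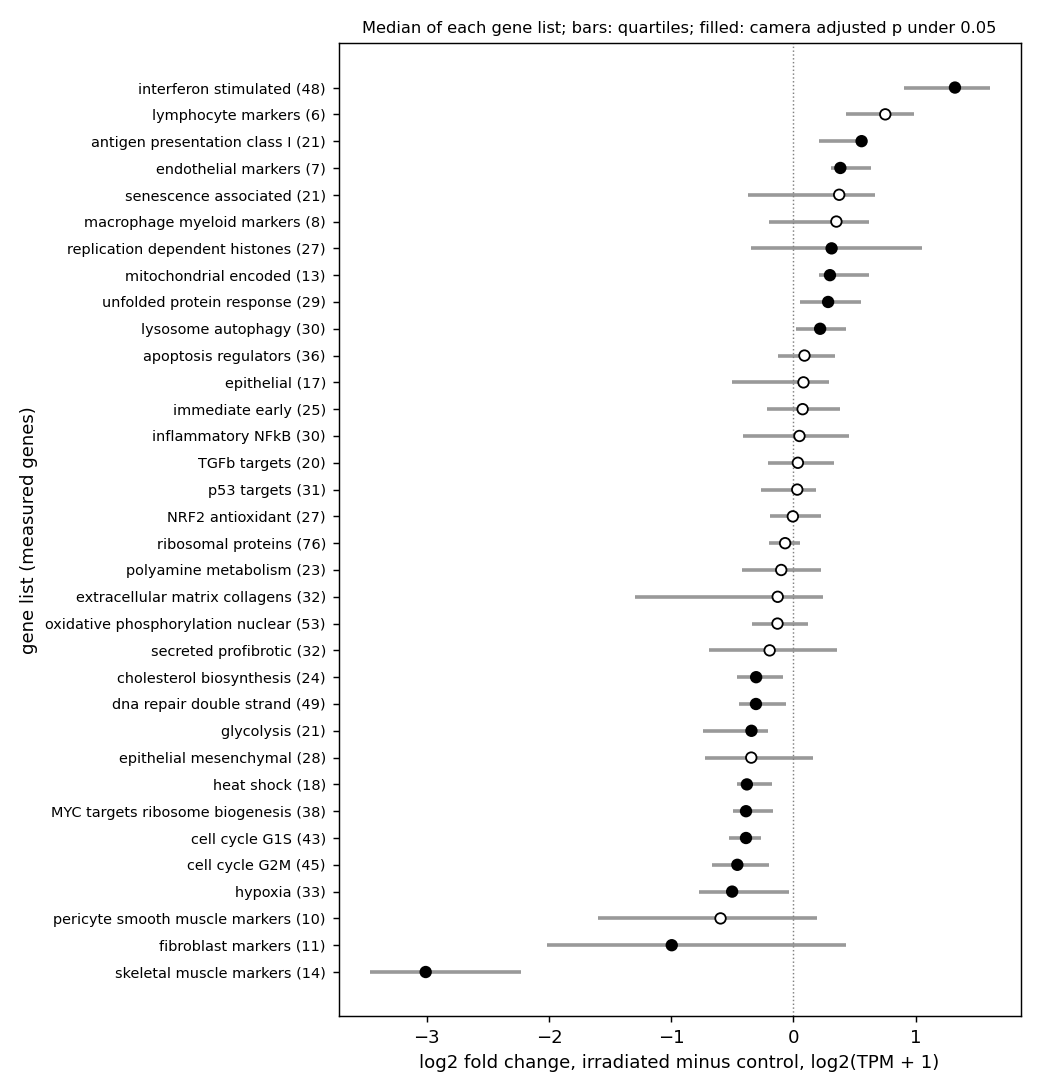
Median log2 fold change (irradiated minus control, log2(TPM + 1) scale, horizontal axis) of each of the 34 tested gene lists, with the number of measured genes in brackets, bars from the lower to the upper quartile, and filled points for a camera adjusted p under 0.05. Interferon-stimulated genes lie highest, at a median of 1.32, and skeletal muscle markers lowest, at -3.01.

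SRM, which makes spermidine from putrescine, did not pass the test, at 156.6 ± 29.7 TPM in controls and 143.7 ± 25.9 TPM in irradiated tumors. Its log2 fold change was -0.12 (95% interval -0.56 to 0.32, limma adjusted p = 0.759), and its level was 178, 123 and 169 TPM in the control tumors and 121, 137 and 172 TPM in the irradiated ones. The gene (ENSG00000116649) lies on chromosome 1 from 11054584 to 11060024 in GRCh38. Spermine synthase (SMS), which acts on the product of SRM, fell from 173.8 ± 6.74 to 103.6 ± 4.27 TPM (log2 fold change -0.74, adjusted p = 0.0183). ODC1, the ornithine decarboxylase that starts the pathway, fell from 146 ± 26.3 to 82.5 ± 4.26 TPM (log2 fold change -0.80, adjusted p = 0.0353). AMD1, which supplies the aminopropyl donor, had a log2 fold change of -0.64 (adjusted p = 0.186), and SAT1, which acetylates polyamines, one of -0.12 (adjusted p = 0.824), neither passing. SLC3A2, a transporter subunit, rose from 125.8 ± 10.6 to 195 ± 6.99 TPM (log2 fold change 0.63, adjusted p = 0.0356). Of 23 measured genes of polyamine metabolism, 1 rose and 2 fell over all genes, and 2 rose and 3 fell adjusted over the list alone. The list as a whole was not called (median log2 fold change -0.099, camera adjusted p = 0.779), and its median ranged from -0.21 to 0.057 without single tumors. The calls of SMS, ODC1 and SLC3A2 were kept without control tumor 2 and lost without any other one tumor, with adjusted p up to 0.0780 for SMS, 0.113 for ODC1 and 0.145 for SLC3A2. All 3 calls were also lost without trend (adjusted p up to 0.0887) and with a replicate block (up to 0.101), and those of ODC1 and SLC3A2 without a filter on low values (up to 0.0925).

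**Figure D2:**
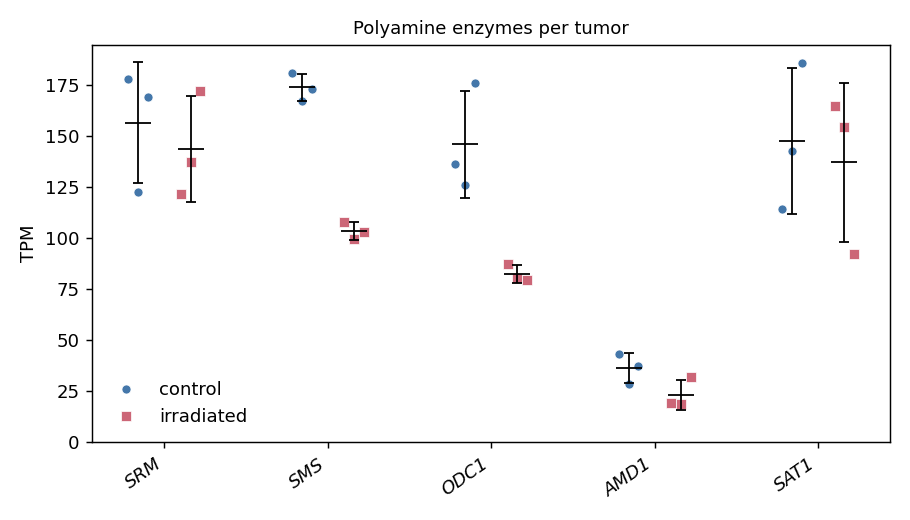
TPM (vertical axis) of 5 polyamine enzymes in each control and irradiated tumor, with horizontal bars at the mean of 3 tumors and error bars of 1 SD. SMS and ODC1 lie lower in all 3 irradiated tumors than in all 3 controls, and SRM overlaps between the groups.

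Interferon-stimulated genes formed the group with the largest rise in its median. OASL, an antiviral oligoadenylate synthetase-like protein, rose from 24.8 ± 13.9 to 181 ± 66.3 TPM (log2 fold change 2.89, limma adjusted p = 0.00943), and its relative OAS1 from 54.2 ± 26.0 to 308 ± 177 TPM (2.44, adjusted p = 0.0292). UBE2L6, the conjugating enzyme for ISG15, rose by 1.53 (adjusted p = 0.0159), and IFITM3, a membrane protein that blocks viral entry, rose from 1642 ± 418 to 4515 ± 1422 TPM (1.44, adjusted p = 0.0274). All 48 measured members had a fold change above 0. In 32 of the 48 the groups did not overlap, against 26.6% of all tested genes and 10% by chance, both over the 2 directions together. Over all genes 10 members rose, and 40 did adjusted over the list alone. The list had a median log2 fold change of 1.32 and a camera adjusted p = 6.5e-25, with adjusted p = 0.593 with an estimated correlation. The summed TPM of the list ranged from 4260 to 8614 in controls and was 25930, 16767 and 11658 in irradiated tumors 1, 2 and 3. The number of members that rose was 0 without control tumor 1, 2 without irradiated tumor 1 or 2, and 7 without any other one tumor, and the list stayed called in each case. OASL and UBE2L6 lost their calls without control tumor 1 alone (adjusted p = 0.0569 and 0.0709), and OAS1 and IFITM3 without control tumor 1, irradiated tumor 1 or irradiated tumor 2 (up to 0.106 for OAS1).

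**Figure D3:**
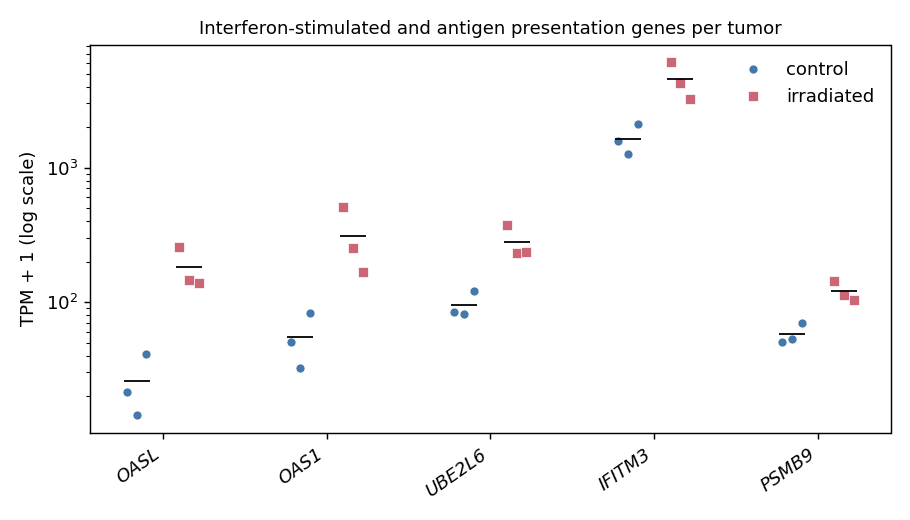
TPM + 1 on a log scale (vertical axis) of 4 interferon-stimulated genes and of PSMB9 in each tumor, with horizontal bars at the group means. For each of the 5 genes the 3 irradiated tumors lie above the 3 controls.

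Genes of class I antigen presentation were higher as a group. PSMB9, an immunoproteasome subunit, rose from 56.8 ± 10.1 to 119 ± 21.4 TPM (log2 fold change 1.06, adjusted p = 0.0251), while the subunits PSMB8 (0.65, adjusted p = 0.0547) and PSMB10 (0.57, adjusted p = 0.0571) did not pass. PSMB9 lost its call without control tumor 1 or any one of the 3 irradiated tumors (adjusted p up to 0.0904). Of 21 measured genes, 1 rose over all genes and 7 adjusted over the list alone. The list had a median of 0.56 (camera adjusted p = 2.3e-05, and adjusted p = 0.593 with an estimated correlation). Genes of inflammatory NFkB signalling had 0 calls of 30 in limma, also adjusted over the list alone, and a median of 0.050 (camera adjusted p = 0.200). That list was called higher without control tumor 3 (camera adjusted p = 0.00264) and without irradiated tumor 3 (1.9e-05), and its direction turned without control tumor 1 (median -0.12) and without irradiated tumor 2 (-0.26).

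Cell-cycle genes were lower as groups, with few single calls. UBE2S, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 456 ± 86.9 to 162 ± 39.4 TPM (log2 fold change -1.50, adjusted p = 0.0132), and ANLN, a scaffold of cytokinesis, fell by 0.87 (adjusted p = 0.0485). These 2 were the only calls among 45 genes of G2 and mitosis, over all genes and adjusted over the list alone. That list had a median of -0.46 (camera adjusted p = 7.3e-07, and adjusted p = 0.593 with an estimated correlation). The G1 and S phase list had 0 calls of 43 in either adjustment and a median of -0.39 (camera adjusted p = 8.6e-05, and adjusted p = 0.639 with an estimated correlation). Genes of double-strand break repair had 0 of 49 in either adjustment and a median of -0.31 (camera adjusted p = 0.00301, and adjusted p = 0.688 with an estimated correlation). The repair median ranged from -0.35 to -0.15 without single tumors. The groups did not overlap in 18 of 45 genes of G2 and mitosis, 11 of 43 of G1 and S phase and 11 of 49 of repair. Of all tested genes 26.6% did not overlap, and only the G2 and mitosis list exceeded that share. The G1 and S phase list summed to 2227, 1353 and 2134 TPM in the controls and 1275, 1486 and 1410 TPM in irradiated tumors, so control tumor 2 lay among the irradiated ones. MKI67, a proliferation marker, was at 47.6, 19.0 and 39.8 TPM in the controls and at 13.4, 18.2 and 19.4 TPM in the irradiated tumors (log2 fold change -0.94, limma adjusted p = 0.154), and passed without control tumor 2 (adjusted p = 0.0214). Without that tumor 12 genes of G2 and mitosis, 8 of G1 and S phase and 3 of repair fell. ANLN lost its call without any other one tumor (adjusted p up to 0.168) and UBE2S without control tumor 1 (0.0584).

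Targets of p53 were not called as a group. MDM2, the ubiquitin ligase of p53, which overlaps another gene on the same strand, fell from 20.8 ± 0.225 to 10.8 ± 2.08 TPM (log2 fold change -0.90, adjusted p = 0.0406), a call kept without control tumor 2 and lost without any other one tumor (adjusted p up to 0.123), and also lost with quantile normalization, with length and GC correction, with a replicate block, without trend and without a filter on low values. CDKN1A, the cell-cycle inhibitor p21, was at 57.2 ± 7.34 and 78.1 ± 17.3 TPM (0.43, adjusted p = 0.247). MDM2 was the only call among 31 targets, over all genes and adjusted over the list alone. The list had a median of 0.032, a mean of -0.040 and a camera adjusted p = 0.797 in the upward direction, which turned without control tumor 1 and without irradiated tumor 1 (medians 0.077 and -0.0056).

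Glycolysis and hypoxia genes were lower as groups. Lactate dehydrogenase A (LDHA) fell from 1479 ± 93.9 to 818 ± 141 TPM (log2 fold change -0.87, adjusted p = 0.0273), the enolase ENO2 from 139 ± 4.16 to 74.3 ± 12.8 TPM (-0.91, adjusted p = 0.0245) and the glucose transporter SLC2A1 from 196 ± 23.6 to 96.5 ± 22.6 TPM (-1.03, adjusted p = 0.0286). With TPI1 and HK2, 5 of 21 glycolysis genes fell over all genes and 11 adjusted over the list alone. This list had a median of -0.34 (camera adjusted p = 9.8e-07, and adjusted p = 0.523 with an estimated correlation), and it was the only list that fry called (adjusted p = 0.0229). Of 33 hypoxia genes 2 fell over all genes, SLC2A1 and HK2, which are in both lists, and 11 adjusted over the list alone. The number of glycolysis genes that fell was 5 without control tumor 2, 2 without irradiated tumor 2 and 0 without any other one tumor, and that of hypoxia genes 2, 1 and 0. Without trend or without a filter on low values it was 0 for each list, and with medians of ratios it was 2 for glycolysis and 1 for hypoxia. The hypoxia list had a median of -0.50 (camera adjusted p = 0.00106, and adjusted p = 0.596 with an estimated correlation), and without control tumor 2 it was not called (camera adjusted p = 0.149).

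Growth-related and heat-shock genes were also lower as groups. Nucleophosmin (NPM1), a nucleolar chaperone of ribosome assembly, fell from 2085 ± 65.1 to 1170 ± 105 TPM (log2 fold change -0.84, adjusted p = 0.0124). Of 38 MYC targets and ribosome biogenesis genes, 4 fell over all genes, namely NPM1, LDHA, ODC1 and HSPE1, and 8 adjusted over the list alone. Without control tumor 2, 10 of them fell, without control tumor 1 or irradiated tumor 1, 1, and without any other one tumor, 2. Their median was -0.39 (camera adjusted p = 1.4e-06, and adjusted p = 0.593 with an estimated correlation). The 18 heat-shock genes had a median of -0.38 (camera adjusted p = 2.9e-04, and adjusted p = 0.593 with an estimated correlation), with 2 that fell over all genes, HSPA1A and HSPE1, and 6 adjusted over the list alone. HSPA1A, an inducible HSP70, fell from 6.71 ± 1.90 to 1.19 ± 0.396 TPM (-1.80, adjusted p = 0.0154), and lost its call without control tumor 1, irradiated tumor 1 or irradiated tumor 3 (up to 0.0664). HSPE1 shares exons with the read-through gene HSPE1-MOB4, and with overlapping genes summed its log2 fold change was 0.24 (adjusted p = 0.367). In cholesterol synthesis, ACAT2 fell by 0.71 (adjusted p = 0.0433) and TM7SF2 rose by 0.96 (adjusted p = 0.0356), the only calls among 24 genes, each lost without any one tumor other than control tumor 2 (adjusted p up to 0.154 and 0.121). Adjusted over the list alone, 1 rose and 3 fell. The cholesterol list had a median of -0.30 (camera adjusted p = 0.00301, and adjusted p = 0.602 with an estimated correlation).

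Lists of the endoplasmic reticulum, lysosome and mitochondrial genome were higher by small amounts. ATF6, a stress sensor of the endoplasmic reticulum, rose from 10.5 ± 0.852 to 21.6 ± 3.20 TPM (log2 fold change 0.97, adjusted p = 0.0273). It was the only one of 29 unfolded protein response genes called over all genes, and 2 rose adjusted over the list alone. That list had a median of 0.28 (camera adjusted p = 1.4e-04, and adjusted p = 0.593 with an estimated correlation). The protease cathepsin Z (CTSZ) rose by 0.72 (adjusted p = 0.0304), alone among 30 genes of lysosome and autophagy, of which 2 rose adjusted over the list alone. Their median was 0.22 (camera adjusted p = 1.9e-04, and adjusted p = 0.593 with an estimated correlation). All 13 mitochondrially encoded genes had fold changes above 0, MT-ND6 rose by 1.25 (adjusted p = 0.0385), and 4 rose adjusted over the list alone. Their median was 0.30 (camera adjusted p = 6.0e-05, and adjusted p = 0.593 with an estimated correlation), and ranged from 0.17 to 0.48 without single tumors. Nuclear genes of oxidative phosphorylation had a median of -0.13 and were not called as a list (camera adjusted p = 0.151). Of those 53 genes NDUFA10 and ATP5F1D fell over all genes, and 5 fell adjusted over the list alone, and that list was called lower without control tumor 3 (camera adjusted p = 0.0169). ATF6 lost its call without any one tumor other than control tumor 2 (adjusted p up to 0.104). CTSZ lost it without control tumor 1 or 3 or irradiated tumor 1 or 2 (up to 0.122), NDUFA10 without the same 4 (up to 0.0856), MT-ND6 without control tumor 1 or 3 or irradiated tumor 1 or 3 (up to 0.126), and ATP5F1D without any one tumor other than control tumor 2 (up to 0.151).

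Skeletal muscle and fibroblast markers were lower as groups. The fast myosin heavy chains MYH1 and MYH4 fell by 2.99 and 3.15 (adjusted p = 0.0437 for each), the calcium store protein CASQ1 fell by 2.22 (adjusted p = 0.0337), which made 3 of 14 measured muscle markers over all genes. All 14 fell adjusted over the list alone, with a median of -3.01. Without irradiated tumor 2, 10 muscle markers fell over all genes, without control tumor 2, 2, and without any other one tumor, 0. Camera called the list (adjusted p = 3.9e-08, and adjusted p = 0.593 with an estimated correlation). Muscle markers summed to 277, 309 and 688 TPM in the controls, and to 4.83, 198 and 7.99 TPM in irradiated tumors 1, 2 and 3. COL1A1, a chain of type I collagen, fell from 460 ± 206 to 114 ± 34.4 TPM (log2 fold change -1.96, adjusted p = 0.0194), COL1A2 by 2.07 (adjusted p = 0.0112) and COL3A1 by 2.29 (adjusted p = 0.0151). These were the 3 calls among 11 fibroblast markers, of which 6 fell adjusted over the list alone, and 1 of them was called without irradiated tumor 1 and 0 without irradiated tumor 3, while COL1A1 lost its call without control tumor 1 as well (0.0554). The fibroblast list had a median of -0.995 (camera adjusted p = 0.00999, and adjusted p = 0.593 with an estimated correlation), and without control tumor 2 it was not called (camera adjusted p = 0.0614). Of its 11 genes 8 had fold changes below 0 and 3 above. Its sum was mostly these 3 collagen genes, with 465 of 509 TPM in control tumor 1 and 126 of 190 TPM in irradiated tumor 1. The labels give human as the organism and do not say how reads from mouse tissue were treated.

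**Figure D4:**
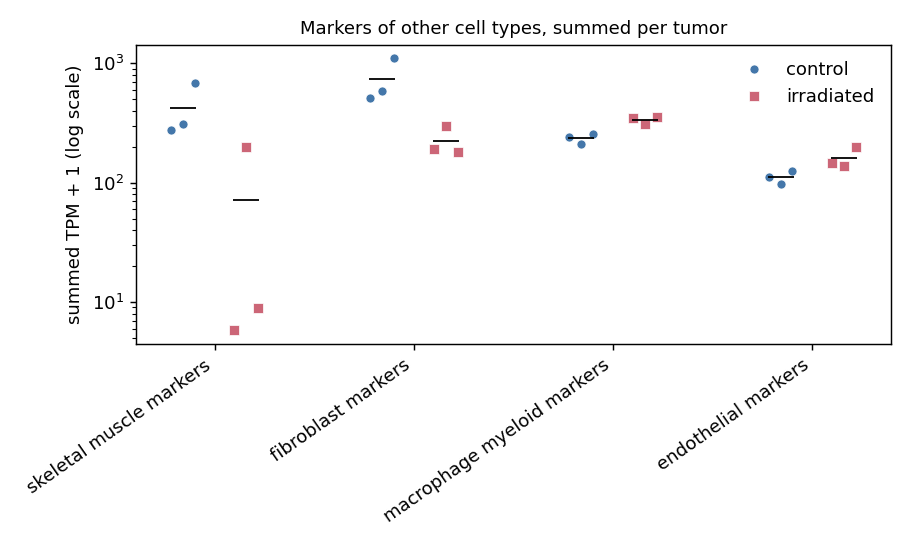
Summed TPM + 1 on a log scale (vertical axis) of 4 lists of markers of other cell types in each tumor, with horizontal bars at the group means. Skeletal muscle markers lie under 10 TPM in irradiated tumors 1 and 3, and fibroblast markers are lower in all 3 irradiated tumors than in all 3 controls.

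Other matrix genes and targets of TGF-beta went in both directions. Of 32 matrix and collagen genes 7 fell over all genes, among them SPARC, a collagen-binding glycoprotein (log2 fold change -1.43, adjusted p = 0.0437), and the proteoglycan BGN (-1.42, adjusted p = 0.0354). Adjusted over the list alone, 11 fell and 4 rose, namely HSPG2, COL6A1, COL6A2 and fibronectin (FN1), which over all genes had adjusted p between 0.0540 and 0.0985. FN1 was at 691 ± 352 and 1429 ± 312 TPM (1.14, adjusted p = 0.0985). The matrix list was not called (median -0.13, camera adjusted p = 0.137), and was called lower without control tumor 1 (0.0141) and without irradiated tumor 2 (0.0135). The number of matrix genes that fell was 2, 6 and 3 without control tumors 1, 2 and 3, and 1, 6 and 0 without irradiated tumors 1, 2 and 3, it was 0 without a filter on low values and 4 without trend, and FN1, COL6A1 and COL6A2 rose without control tumor 2 (adjusted p = 0.0146, 0.0459 and 0.0477). Among 20 targets of TGF-beta, ID1 rose from 16.3 ± 1.62 to 45.5 ± 9.09 TPM (1.41, adjusted p = 0.00740), and ID3 (2.32) and BAMBI (1.17) rose as well. ACTA2, the smooth muscle actin, fell from 182 ± 34.1 to 51.0 ± 22.3 TPM (-1.88, adjusted p = 0.0174), and TAGLN (-1.83), CCN2 (-1.38) and BHLHE40 (-0.59) fell too. Adjusted over the list alone 4 rose and 4 fell, and the list was not called (median 0.037, camera adjusted p = 0.439). The targets that rose numbered 3 without control tumor 2 and 1 without any other one tumor, and those that fell 3 without control tumor 2 or irradiated tumor 3, 1 without irradiated tumor 1 and 0 without the remaining ones. Of 32 secreted profibrotic factors GDF15 rose (1.26, adjusted p = 0.0323) and CCN2 fell, with 2 that rose and 3 that fell adjusted over the list alone, and the list was not called (median -0.19, camera adjusted p = 0.660), and the direction of its test, though not its median, turned without control tumor 2 (median -0.19), while both turned without irradiated tumor 1 (0.020). GDF15 lost its call without any one tumor other than control tumor 2 (adjusted p up to 0.134). CCN2 lost its call in 5 of the 6 fits that leave out 1 tumor (adjusted p up to 0.101).

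Lists of senescence, mesenchymal, epithelial, ribosomal protein and several stress genes were not called. Senescence-associated genes had a median of 0.38 (camera adjusted p = 0.0584), with PLAT, GDF15 and GLB1 the 3 of 21 that rose, over all genes and adjusted over the list alone. PLAT, tissue plasminogen activator, rose from 32.2 ± 0.875 to 62.6 ± 3.88 TPM (log2 fold change 0.94, limma adjusted p = 0.0112), and lost its call without irradiated tumor 1 (0.0649), while GLB1 lost it without any one tumor (up to 0.171). The senescence list was called without control tumor 2 (camera adjusted p = 0.0288), control tumor 3 (0.0139) and irradiated tumor 3 (0.00110). Its median ranged from 0.054 to 0.55 without single tumors, with camera adjusted p up to 0.374. Mesenchymal genes had 3 of 28 that fell, SPARC, TAGLN and TPM1, and adjusted over the list alone 1 rose and 7 fell (median -0.34, camera adjusted p = 0.0915), and the list was called lower without control tumor 1 (0.0188) and irradiated tumor 2 (0.0135). Of 17 epithelial genes the protease ST14 rose (1.30, adjusted p = 0.0242) and the mucin MUC1, which overlaps another gene on the same strand, fell (-1.55, adjusted p = 0.0228), with 2 and 1 adjusted over the list alone (median 0.083, mean -0.021, camera direction upward, adjusted p = 0.679), and the direction turned without irradiated tumor 1 (median -0.020). ST14 lost its call without any one tumor other than control tumor 2 (up to 0.103), and MUC1 without control tumor 1 or 3 or irradiated tumor 2 or 3 (up to 0.0770). The 76 ribosomal protein genes (median -0.067, camera adjusted p = 0.581), 27 NRF2 targets (median -0.0040, camera direction upward, adjusted p = 0.430) and 36 regulators of apoptosis (median 0.091, camera adjusted p = 0.0915) had 0 calls each in limma in either adjustment. The ribosomal protein list was called lower without control tumor 1 (0.0125) and control tumor 3 (0.0139) and higher without control tumor 2 (median 0.058, 1.2e-04), and the apoptosis list higher without irradiated tumor 3 (0.0279). The 25 immediate early genes had 0 calls over all genes and 1 that fell adjusted over the list alone (median 0.076, camera adjusted p = 0.430).

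Markers of the other cell types had medians nearer 0 than those of muscle. Of 7 endothelial markers 0 rose over all genes and 1 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.0353, and adjusted p = 0.596 with an estimated correlation). Without control tumor 1, control tumor 2 or irradiated tumor 3 the endothelial list was not called (camera adjusted p = 0.0700, 0.0950 and 0.195). Its median ranged from 0.092 to 0.57 without single tumors. Of 10 pericyte and smooth muscle markers ACTA2 and TAGLN fell and MCAM rose, with 3 that fell and 1 that rose adjusted over the list alone (median -0.60, camera adjusted p = 0.200). MCAM lost its call without any one tumor (adjusted p up to 0.120). The 8 myeloid markers (median 0.35, camera adjusted p = 0.151) and the 6 lymphocyte markers (median 0.75, camera adjusted p = 0.0831) had 0 calls in either adjustment. The myeloid list was called without control tumor 3 (0.0301), and the lymphocyte list without control tumor 3 (0.0333) and irradiated tumor 1 (0.0129). Since NSG mice lack T, B and natural killer cells, the lymphocyte values are not read as lymphocytes in the tumors. Lists with fewer than 5 measured genes were not tested: keratinocyte markers (2 measured, of which the keratin KRT10 fell, with a log2 fold change of -1.62 and a limma adjusted p = 0.00255), Schwann cell markers (4 measured, 0 called), erythroid markers (1 measured, 0 called) and adipocyte markers (0 measured).

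Many of the largest single changes were in genes whose reads are hard to assign, and in some, though not all, the sum with a neighbor or copy overlapped between the groups. HSPE1-MOB4, a read-through of adjacent genes on chromosome 2 (197500413 to 197550726), was listed at 3.86 ± 2.47 TPM in controls and 357 ± 26.8 TPM in irradiated tumors (log2 fold change 6.34, adjusted p = 9.4e-05), while HSPE1 fell from 426 ± 64.2 to 154 ± 12.5 TPM. Their sum with MOB4 was 450 ± 63.2 and 528 ± 19.6 TPM, with all 3 irradiated tumors above the controls. PIGY was listed at 0 in all 3 controls and at 39.0 ± 2.66 TPM in irradiated tumors, where its values were identical to those of PYURF, with which it shares exons. PYURF was at 106 ± 7.28 TPM in controls, and the sum of both was 78.1 ± 5.32 TPM in irradiated tumors, below all controls. SERF1A rose from 1.09 ± 0.624 to 22.6 ± 2.21 TPM (3.53, adjusted p = 2.7e-04) while its near-identical copy SERF1B had 35.2 ± 6.38 and 13.3 ± 3.35 TPM, with sums of 36.3 ± 6.90 and 35.9 ± 4.66 TPM. IL4I1, which overlaps NUP62, rose by 3.01 (adjusted p = 2.4e-04), and their sum was 47.7 ± 11.6 and 47.0 ± 4.46 TPM. In the other direction the read-through genes ATP6V1G2-DDX39B (-3.42, adjusted p = 2.0e-05) and P2RX5-TAX1BP3 (-3.44, adjusted p = 2.7e-04), the pseudogene EEF1A1P5 (-2.80, adjusted p = 6.3e-04), and PDF (-2.84) fell. The neighbors DDX39B (247 ± 50.8 and 239 ± 39.2 TPM) and TAX1BP3 (145 ± 9.11 and 134 ± 19.4 TPM) were not higher in irradiated tumors on average, and the sum of P2RX5-TAX1BP3, TAX1BP3 and P2RX5 was 191 ± 22.0 and 144 ± 17.3 TPM, without overlap between the groups. NPM1P51 and CEACAM6 were listed at 0 in all irradiated tumors, CEACAM6 with its call lost without any one tumor other than control tumor 1 (adjusted p up to 0.0904), and FRG1KP, ARMC10P1 and RNA5S11 at 0 in all controls. The antisense gene ABALON fell by 2.77 and the pseudogene PPP1R14BP4 rose by 4.94, and strand use in counting is not given in the sources used here.

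**Figure D5:**
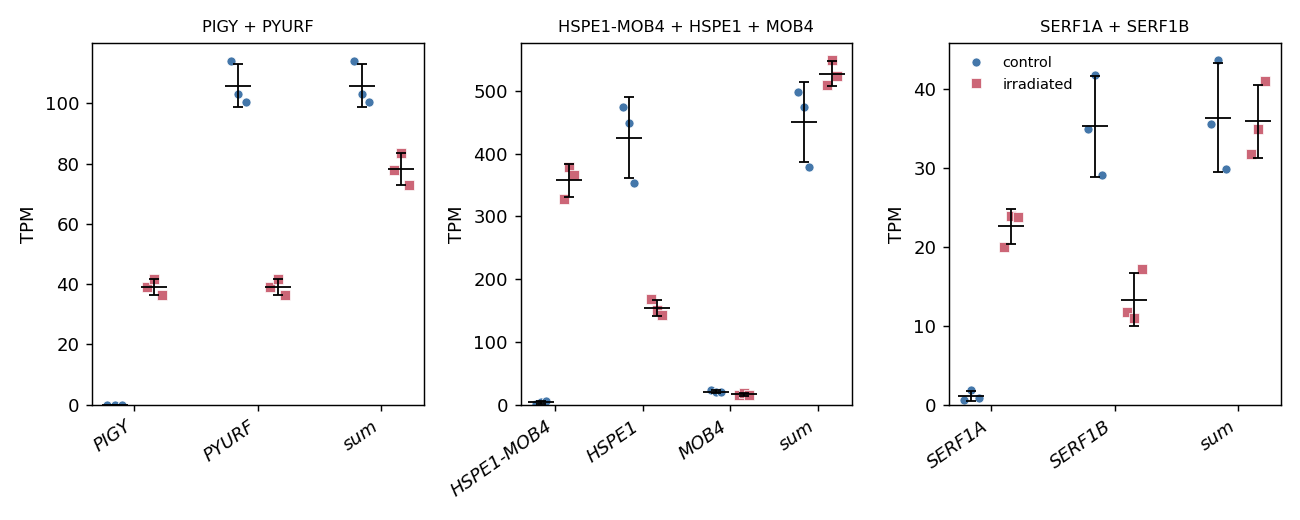
TPM (vertical axis) of neighboring or duplicated genes and of their sums in each tumor, with horizontal bars at the mean of 3 tumors and error bars of 1 SD. The sum of SERF1A and SERF1B was 36.3 TPM in controls and 35.9 TPM in irradiated tumors, while each gene alone differed between the groups.

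Some of the largest changes were in protein-coding genes without a same-strand overlap. FRAS1, an extracellular matrix protein, was at 0.113 ± 0.0569 TPM in controls and 34.98 ± 11.3 TPM in irradiated tumors (log2 fold change 4.97, adjusted p = 4.6e-05). NUPR1, a stress-induced nuclear protein, rose from 0.560 ± 0.446 to 12.1 ± 4.34 TPM (3.04, adjusted p = 0.00335), and FAM220A rose by 3.01 (adjusted p = 5.7e-04). IL1RAPL2 (-4.10, adjusted p = 4.0e-05), SPTBN5 (-4.10, adjusted p = 2.8e-04) and TP53TG5 (-3.08, adjusted p = 0.0413) fell, the last with its call lost without any one tumor other than control tumor 1 (up to 0.122). FRAS1, IL1RAPL2 and SPTBN5 were among 37 genes all but absent in one group, most of which were not protein-coding genes without overlap. Among histone genes of the replication-dependent clusters, H2AC6 rose from 7.44 ± 0.770 to 39.2 ± 3.04 TPM (2.25, adjusted p = 2.7e-04), and H2BC12 (1.47), H4C8 (1.99), H4C14 (1.71) and H2BC5 (1.33) rose too. These were 5 of 27 measured genes, and adjusted over the list alone 9 rose and 3 fell. Over all genes 3 rose without irradiated tumor 1 or without irradiated tumor 3. The histone list had a median of 0.31 (camera adjusted p = 0.00287, and adjusted p = 0.593 with an estimated correlation). By class, 2.19% of 9806 protein-coding genes without a same-strand overlap were called, against 7.63% of 655 pseudogenes and 15.8% of 76 read-through genes. The deposited TPM summed to between 998020 and 998569 in controls and between 992259 and 994773 in irradiated tumors.

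Calls of genes named above also depended on settings other than the tumors used. Without trend, ACAT2, ANLN, ATP5F1D, BGN, BHLHE40, CCN2, CTSZ, ENO2, GLB1, HK2, ID3, IFITM3, LDHA, MCAM, MDM2, MT-ND6, MYH1, MYH4, OAS1, ODC1, PSMB9, SLC2A1, SLC3A2, SMS, SPARC, TM7SF2, TP53TG5, TPI1 and TPM1 lost their calls. With a replicate block, ACAT2, ANLN, ATF6, ATP5F1D, BAMBI, BGN, BHLHE40, CASQ1, CTSZ, ENO2, GDF15, GLB1, HK2, MCAM, MDM2, MYH1, MYH4, NDUFA10, ODC1, PSMB9, SERF1B, SLC3A2, SMS, SPARC, ST14, TM7SF2, TP53TG5, TPI1 and TPM1 did. With a pseudocount of 5, ANLN, CASQ1, CEACAM6, MYH1, MYH4, SPARC and TP53TG5 lost their calls, and with one of 0.1, MYH1 and MYH4. With medians of ratios, BHLHE40, GLB1, LDHA, SLC2A1, SPARC and TPI1 lost them, with robust estimates, ID3, MYH1, MYH4, OAS1, SPARC and TP53TG5, and with length and GC correction, CTSZ, GLB1, HK2, MDM2, SLC3A2 and SPARC. Quantile normalization ended the call of MDM2, and a minimum of 5 TPM that of GDF15. Without a filter on low values, the genes that kept their calls were ABALON, ARMC10P1, ATP6V1G2-DDX39B, EEF1A1P5, FAM220A, FRAS1, FRG1KP, H2AC6, H2BC12, H4C8, HSPE1, HSPE1-MOB4, ID1, IL1RAPL2, IL4I1, KRT10, NDUFA10, NPM1P51, NUPR1, P2RX5-TAX1BP3, PDF, PIGY, PLAT, PPP1R14BP4, PYURF, RNA5S11, SERF1A, SMS and SPTBN5.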

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

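The fits on genes without overlap, on summed genes, with length and GC correction, and without both second replicates were chosen after seeing the data. SRM had a log2 fold change below 0 and did not pass in any of the alternatives run for it, from -0.29 to -0.0073 without single tumors. The 421 calls (194 higher, 227 lower) stayed within 1.5 times under pseudocounts of 0.1 and 5, a minimum of 5 TPM, medians of ratios, leaving out mitochondrial and ribosomal protein genes, robust estimates, genes without overlap, and length and GC correction, as did the total and the lower calls under quantile normalization, where 309 were higher. The fit on genes without overlap tested 9806 genes, which left out 206 of the 421 calls. Its 304 calls included 215 of the 421. Without a filter there were 133 calls (69 higher, 64 lower) among 30037 genes tested. Without trend there were 279 (142 lower), with sample weights 1064 (426 higher, 638 lower), and with a minimum fold of 1.5, 71. With overlapping genes summed 139 were lower. Without both second replicates there were 186 (61 higher, 125 lower). Leaving out 1 tumor gave 127 to 791 calls, 57 to 229 higher and 67 to 562 lower. The cause was not tested. Of the 17 list calls, 0 stood with an estimated correlation and 1 with fry. Of 126 genes named by the rule besides SRM, calls were lost for 41 without a filter, 25 without trend and 33 without both second replicates, and gained for 26 with sample weights. Members of the interferon list called over all genes, 10 as reported, were 0 without a filter, 2 without trend, 1 without both second replicates, 15 at 5 TPM and also without mitochondrial and ribosomal protein genes, 17 with quantile normalization and also over genes without overlap, 18 with length and GC correction and 21 with sample weights. Without both second replicates 1 glycolysis gene and 0 polyamine genes were called. Muscle markers that fell, 3 as reported, were 0 with a pseudocount of 5 or without a filter, 1 with a pseudocount of 0.1, without trend or with robust estimates, 5 over genes without overlap and 8 without both second replicates. The endothelial call was also lost without a filter, without trend, with quantile normalization, sample weights, length and GC correction, or without mitochondrial and ribosomal protein genes, the hypoxia call with sample weights, and the fibroblast call without a filter. GLB1, ANLN and PYURF lost their calls with overlapping genes summed.

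With a replicate block 185 genes were called (88 higher, 97 lower), 24 of the 126 genes lost their calls, 0 polyamine genes, 2 glycolysis genes and 1 muscle marker were called, and the lymphocyte list was the only list to change, to adjusted p = 0.0458. Tumors of the same number did not deviate together (r = -0.043, -0.046 and -0.059 across genes), and 0 of the 3 pairs matched best by number. No pairing by number shows in these values, though 3 pairs are too few to exclude one.

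Among named genes HSPE1 turned to 0.24 with overlapping genes summed, and SAT1 ranged from -0.29 to 0.14 without single tumors. Ribosomal protein genes turned to medians of 0.058 without control tumor 2 (range -0.13 to 0.058), where the list was called (camera adjusted p = 1.2e-04), 0.059 without both second replicates (1.9e-04), and were tested upward at -0.0028 with sample weights. Other lists turned in the direction of their camera test and were not called in the settings where they did. By median, these were epithelial (-0.15 at 5 TPM, 0.0079 with length and GC correction), p53 targets (-0.049 with sample weights, 0.032 with fry), secreted profibrotic (-0.16 with sample weights), NFkB (-0.44 without both second replicates), immediate early (0.068 with length and GC correction, 0.0022 without both second replicates) and oxidative phosphorylation (-0.087 without both second replicates). Without single tumors, where the test of the first 4 of these lists turned at least once and that of the other 2 did not, the medians ranged from -0.020 to 0.10 (epithelial), -0.10 to 0.10 (p53 targets), -0.28 to 0.020 (secreted profibrotic), -0.26 to 0.46 (NFkB), -0.14 to 0.27 (immediate early) and -0.15 to -0.078 (oxidative phosphorylation). Without both second replicates the tests of the epithelial, p53 and profibrotic lists kept their direction, at medians of -0.054, -0.14 and -0.38.

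The 6 samples can be split into 3 and 3 in 10 ways, which are too few for a share under 0.05. The real split gave 421 calls, where 5 was the highest of the others, with 194 higher and 227 lower against at most 3 in a direction, and in each case 1 of the 10 splits, the real one, gave as many. For lists 2 of the 10 splits gave 17 or more, the highest other being 19, for control tumors 1 and 2 with irradiated tumor 3. Every split that mixed the groups called lists, from 6 to 19, so the 17 list calls do not set the real split apart. What depth limits is unknown.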

Other observations

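Among the tests below, those on identical values, on the share of genes without overlap, on interferon-stimulated genes without overlap, on read-through genes, on collagen against muscle and on myeloid markers were chosen after the results they measure had been seen, at least in part. The correction for length and GC content was also chosen after seeing the data.

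Histone genes of the replication-dependent clusters did not move together. The genes H2AC6, H2BC5, H2BC12, H4C8 and H4C14 rose, while H3C2, H1-4 and H2AC12 had log2 fold changes of -0.91, -1.10 and -1.28 and were lower adjusted over the list alone, in tumors where the S phase list was also lower. Most transcripts of these clusters end without a poly(A) tail. No explanation was tested.

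A set of 37 genes, 21 listed in irradiated and 16 in control tumors, was all but absent in one group, at no more than 5% of the lowest value of the other group, where it reached at least 2 TPM, and at most 5 genes did so in any other split of the 6 samples. Of the 37, 89.2% were not protein-coding genes free of overlap, against 30.5% of the other tested genes (Fisher's exact test, p = 1.7e-13, across genes, which are not independent), and among the 421 calls the share was 48.9%. A different use of strand for all genes is argued against by the 519 antisense genes. Their median was 0.076 above that of protein-coding genes without overlap (95% bootstrap interval 0.038 to 0.13). The interval lies above 0, the scale understates changes of low genes, and a median does not speak for single genes among the 37. An effect of strand on some of them therefore stays open. More transcription through gene ends in irradiated tumors stays open, since 4 read-through genes rose and 8 fell (exact binomial test, two-sided, p = 0.388). A candidate explanation that also stays open, because it would coincide with irradiation, is that the groups were quantified on different gene models or settings. Apart from PIGY and PYURF, 9 pairs of genes had identical values in the 3 samples of one group only, against 0 in every other split. Of these 9 pairs, 7 are RNA5-8SN5 with its copies, so they are too few separate genes to decide. The shortfall of summed TPM also separated the groups, at 0.143% to 0.198% in controls and 0.523% to 0.774% in irradiated tumors. What the missing share held is not known, so it does not decide either.

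The rise of interferon-stimulated genes was weighed against such differences in processing. Over the 42 members that are protein-coding without overlap the median log2 fold change was 1.35. That could hardly have come out low, since leaving out genes keeps the values of the rest and the lower quartile of all 48 was 0.90. It therefore does not decide on gene models, which stay open. After correction for transcript length and GC content the median was 1.39 over 48 members, which argues against biases with length or GC content as the whole source of the rise. The dose of 10 Gy remains an open explanation that may account for it, as do other differences between the groups that the labels do not record and any reads from mouse cells, which were not tested.

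Muscle and collagen transcripts were lower together in irradiated tumors. If collagen transcripts came with pieces of skeletal muscle on top of a fixed part from other cells, the sum of COL1A1, COL1A2 and COL3A1 would follow the muscle markers along the line of the 3 controls. It did so in irradiated tumors 1 and 3, at 126 and 138 TPM where the line gives 127 and 131 TPM, but in irradiated tumor 2 it was 206 TPM where the line gives 374 TPM, 1.81 times as much. With a line through 3 tumors and 1 tumor away from it, muscle pieces as a source of the collagen change cannot be told apart from a change caused by irradiation. A lower share of all host cells may contribute and stays open too. Myeloid markers had a median of 0.35, but only 2 of 8 lay between 5 and 20 TPM in controls. In that range neither a high level in the tumor cells nor the floor would hide a change. Summed myeloid (235 ± 24.0 and 336 ± 23.6 TPM) and endothelial markers (110 ± 13.9 and 160 ± 33.3 TPM) were higher in irradiated tumors, without overlap. Summed pericyte and smooth muscle markers were lower (431 ± 124 and 187 ± 57.5 TPM). The part of these sums that came from tumor cells is not known.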
